A study of Homo sapiens with 12 samples.

How the data were processed

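Gene expression was measured by RNA sequencing in 12 libraries of the human lung cancer lines NCI-H1975 and HCC827, 6 in a compound experiment and 6 in an siRNA experiment, with RNA extracted with Trizol and libraries made with an Illumina TruSeq kit, per the labels' protocols. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library), per the file headers, in 1 table per experiment with 2 decimals. Bowtie 0.12.2 and the builds mm8 and GRCh38.p12 are named per the submitters' processing notes without a role; mm8 is a mouse build. The quantification tool, the annotation and the use of strand are not given in the sources used here. The unit was taken from the column names.

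The 18E table had 16800 lines, of which 16760 were complete genes; 20 genes lacked the NCI-H1975 values and 20 lines held only spilled annotation text, and these were left out. The siRNA table had 17462 lines, of which 17442 were complete genes and 20 spilled text. Both tables held 16426 genes. Columns were matched to samples by their names, and 0 columns of per-sample values were left unmatched. Of symbols found in a RefSeq gene reference, 99.8% in the 18E table and 99.7% in the siRNA table were protein-coding. Mitochondrially encoded genes were not analysed here. Ratios of low values between libraries did not show steps of whole reads, so counts were not recovered and depth is unknown; an exact 0 is reported as listed at 0. Libraries differed in total FPKM and in genes listed at 0 (534 to 2212).

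Values were transformed to log2(FPKM + 1), so fold changes are on that scale and understate those of low genes. Genes with at least 1 FPKM in at least 2 of the 6 libraries of an experiment were tested, 11953 for 18E and 11718 for siDYN. Tests used limma 3.58.1 in R 4.3.3 with a trend in the prior variance, two-sided, with Benjamini-Hochberg adjusted p under 0.05, and cell line as a block. With 1 library per line and treatment, the residual (2 degrees of freedom for 18E, 3 for siDYN) is the disagreement of the lines, of the siRNAs or of both, and nothing in the labels says that lines were cultured more than once. The difference between lines was an interaction term in which the doses or the siRNAs stood in for replicates. The direct test of the doses came from the same fit. The tables were each tested on their own, and changes, never levels, were set side by side across them.

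The 28 gene lists, the tests and the alternatives were fixed before the data were examined; 26 lists had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members are called over all genes and again adjusted over the list alone. No list passed camera with an estimated correlation in any comparison. That test had little power here. In simulated data it gave 30 uncorrelated genes, all shifted by 0.5, an unadjusted p of 0.0122 at 5 µM and 0.00241 for siDYN. Alone among 26 lists neither would pass after adjustment. A lost call by this test therefore does not show that a list was unchanged. The simulated genes were uncorrelated, so they do not show that the preset correlation was sound. In the 18E fit the estimated correlation was 0.93 for interferon-stimulated genes, 0.88 for heat shock genes and 0.39 for G2 and mitosis genes. It was 0.03 for ATF4 targets and -0.03 for mTORC1 and AMPK regulators. Where members correlate above 0.01, camera at the preset value gives p-values that are too small. In the fry test of a shared direction, 1 list passed, the epithelial markers with siDYN (down, adjusted p = 0.0161). Lists were also tested for the direct comparison of doses and for the difference between the lines, a choice made after the data were seen. For single libraries, list medians were ranked among 10000 random lists of the same size matched on mean expression. Markers of blood, endothelial and stromal cells were at or below 1.38 FPKM in all libraries, except CD14 (up to 10.7 FPKM) and CD68 (32.7 to 229 FPKM), a lysosomal protein.

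Named genes were, for each of the 3 main comparisons, those past the threshold and of one sign in every treated library, filled to 10 per direction with the genes of the largest smallest change over the treated libraries; up to 4 members of each list with the largest fitted change; the dynein and dynamin candidates; and the 5 genes per direction with the smallest p of the difference between lines. Further members named were chosen after their values were seen. Fold changes of sets of 200 genes chosen in one experiment were tested with camera in the other. Coordinates are from GENCODE 29 on GRCh38, as are transcript length and GC content (98.8% and 98.7% of genes matched).

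Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, equal FPKM totals, no variance trend, no line term, pooled doses, single siRNAs, and each library left out. Removal of a GC and length trend, by natural splines with 5 degrees of freedom each, and a threshold of 0.1 were added after the data were seen. With equal totals the median change of all genes moved to -0.19 in NCI-H1975 and -0.17 in HCC827 at 5 µM, and to -0.12 and -0.11 with siDYN-1. When 1 library was left out, the lone library at a level was assumed to vary like the others. In simulated data for the 5 µM comparison (11953 genes, 200 changed), variances were drawn from the fitted prior. The fit called 16.4% of genes changed by 1 on the log2 scale and 92.5% of those changed by 2. For siDYN (11718 genes) it called 58.2% and 92.5%. Each simulated change was the same in both lines, so these shares do not cover genes whose response differs in size between the lines. In the data HSPA6, at 7.61 with 5 µM 18E, had adjusted p = 0.100 with limma, and DYNC1LI1, at -2.48 with siDYN, 0.0784. The simulation was written after the fits to the data had been run, and a first version that drew from the moderated variances, which spread too little, was replaced. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.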

Results

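RNA sequencing was analysed in NCI-H1975 and HCC827, established human non-small cell lung cancer lines that carry activating EGFR mutations. In the compound experiment each line received DMSO, 2.5 µM 18E or 5 µM 18E, with 24 h given for the 18E samples. In the siRNA experiment each line received a control siRNA (siCON) or 1 of 2 siRNAs labelled siDYN-1 and siDYN-2, with 48 h given for the siDYN samples. There was 1 library per line and treatment, 12 in all, so the lines served as the replicates of each treatment (n = 2 lines) and p-values measure the disagreement of these libraries. The series title names LIC1, an alias of DYNC1LI1, which encodes a light intermediate chain of the cytoplasmic dynein motor, and autophagy. The values were FPKM without read totals, so the depth of each library is unknown. FPKM totals ran from 486409 in HCC827 with DMSO to 685680 in NCI-H1975 with siDYN-2.

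DYNC1LI1 was lower with both siRNAs in both lines. It lies on the minus strand of chromosome 3 at 32525971 to 32570874 (GRCh38, GENCODE 29), as a protein-coding gene with up to 13 exons in a transcript. In NCI-H1975 its level was 23.73 FPKM with siCON, 5.1 with siDYN-1 and 3.04 with siDYN-2, which is 21.5% and 12.8% of siCON. In HCC827 it was 16.28 FPKM with siCON, 2.42 with siDYN-1 and 1.22 with siDYN-2, which is 14.9% and 7.49% of siCON. Other dynein genes had smaller changes: DYNC1H1, the motor heavy chain, had a log2 change of -0.52 ± 0.14 (SE) and DYNC1LI2, the paralogous light intermediate chain, -0.47 ± 0.13. With DYNC1LI1 these were the 3 of 16 tested members of the dynein and dynamin list that fell when adjusted over the list alone, and 0 passed over all genes. The list went both ways: 10 members had negative and 6 positive fitted changes, and 4 were higher in all 4 libraries. Among these was DYNLL2, with log2 changes of 0.43 and 1.17 in NCI-H1975 and 0.19 and 0.49 in HCC827 with siDYN-1 and siDYN-2. No member rose when adjusted over the list alone. With 18E, DYNC1LI1 was 21.35 FPKM with DMSO, 26.54 at 2.5 µM and 29.43 at 5 µM in NCI-H1975, and 13.62, 13.08 and 25.03 FPKM in HCC827 (log2 change at 5 µM 0.64 ± 0.22, adjusted p = 0.15).

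**Figure D1:**
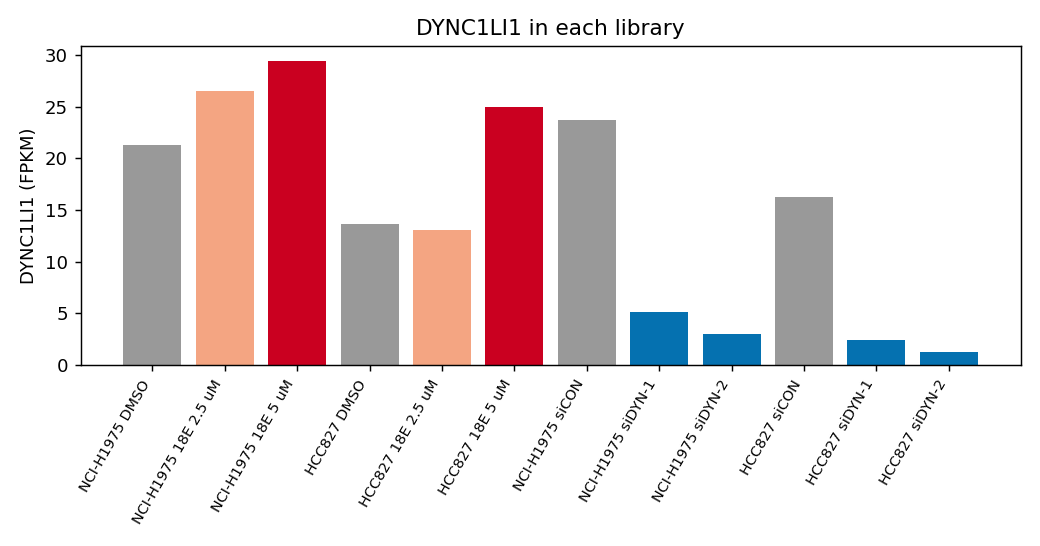
DYNC1LI1 level in FPKM (bars, from 0) in each of the 12 libraries; grey bars are controls, light orange and red bars 18E at 2.5 and 5 µM, and blue bars siDYN. The 4 siDYN libraries lie between 1.22 and 5.1 FPKM, and all the others at 13.08 FPKM or above.

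The first question was which genes responded to 5 µM 18E. ATF4-dependent stress genes were higher, with a median log2 change of 0.74 over 34 tested targets of the integrated stress response. Cells start this programme when translation initiation is curbed. ATF3, a stress-induced transcription factor, went from 5.36 to 60.79 FPKM in NCI-H1975 and from 6.48 to 433.7 FPKM in HCC827 (log2 change 4.57 ± 0.56, SE). DDIT3 (CHOP), a transcription factor of prolonged stress, went from 18.23 to 156.07 and from 18.7 to 402.27 FPKM (3.69 ± 0.31). SESN2, a stress-induced inhibitor of mTORC1 signalling, had a log2 change of 2.69 ± 0.29, and PPP1R15A, which directs the dephosphorylation of eIF2α, 2.50 ± 0.37. The list rose relative to the other genes (camera, adjusted p = 8.86e-12; adjusted p = 0.563 with an estimated correlation). Of its 34 members 23 were higher in both lines, and 16 rose and 1 fell when adjusted over the list alone, against 0 over all genes.

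Some genes of the autophagosome machinery were higher at 5 µM in both lines. GABARAPL1, which encodes a protein that coats the autophagosome membrane, went from 4.61 to 18.81 FPKM in NCI-H1975 and from 12.44 to 175.05 FPKM in HCC827 (log2 change 2.77 ± 0.43), and MAP1LC3B (LC3B) from 61.24 to 131.05 and from 31.3 to 285.65 FPKM (2.12 ± 0.46). MAP1LC3B2, a near-identical copy that may share reads with MAP1LC3B, had 2.21 ± 0.50, and WDR45, which binds phosphoinositide on forming autophagosomes, 1.28 ± 0.29. The related GABARAP had 0.24 ± 0.15 and GABARAPL2 0.01 ± 0.15, named here because of their relatives. The 37 tested genes of the autophagosome machinery rose as a group (median 0.24, camera adjusted p = 0.00126; adjusted p = 0.563 with an estimated correlation). Of these 17 were higher in both lines and 11 had negative fitted changes, and 5 rose when adjusted over the list alone against 0 over all genes. That group call rested on 1 library: without HCC827 at 5 µM the median was 0.04 and adjusted p = 0.0961. SQSTM1 (p62), the receptor that links ubiquitinated cargo to LC3, went from 171.39 to 548.57 FPKM and from 120.57 to 1087.44 FPKM (2.42 ± 0.34). It was the 1 of 15 autophagy receptors that rose when adjusted over the list alone. The receptors as a list did not pass (median 0.09, adjusted p = 0.0826), nor did 37 lysosome genes (median 0.05, adjusted p = 0.127), of which MCOLN1, a lysosomal calcium channel (1.13 ± 0.17), rose when adjusted over the list alone. The mTORC1 and AMPK regulators had a median of 0.05 (adjusted p = 0.334).

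Mitotic genes were lower with 5 µM 18E. All 35 tested genes of the G2 and mitosis list had negative fitted changes (median -0.91), 34 of them lower in both lines. Of these 31 fell when adjusted over the list alone against 0 over all genes. TOP2A, the topoisomerase of dividing cells, went from 136.02 to 66.1 FPKM in NCI-H1975 and from 132.77 to 18.13 FPKM in HCC827 (log2 change -1.92 ± 0.44). MKI67, the proliferation marker Ki-67, had -1.68 ± 0.23 and CENPF, a kinetochore protein, -1.59 ± 0.24. The list fell relative to the other genes (camera, adjusted p = 3.79e-12; adjusted p = 0.563 with an estimated correlation). The G1/S and DNA replication list fell too (median -0.52, adjusted p = 6.81e-05; adjusted p = 0.563 with an estimated correlation), with 15 of 32 members lower and 1, cyclin E1 (CCNE1, 1.26 ± 0.24), higher when adjusted over the list alone. Among p53 targets (median 0.19, adjusted p = 0.0153; adjusted p = 0.563 with an estimated correlation) 5 of 21 rose when adjusted over the list alone, among them CDKN1A (p21), an inhibitor of cyclin-dependent kinases (2.67 ± 0.43), and BBC3 (PUMA), a pro-apoptotic BCL2 family member (2.03 ± 0.37).

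Heat shock genes had a median log2 change of 1.93 in HCC827 and 0.43 in NCI-H1975 at 5 µM; the difference between the lines over both doses did not pass (adjusted p = 0.0544). All 19 had positive fitted changes (median 1.18, camera adjusted p = 4.16e-09; adjusted p = 0.563 with an estimated correlation), 9 of them past the threshold when adjusted over the list alone. HSPA6, an inducible HSP70, went from 1.3 to 104.12 FPKM in NCI-H1975 and from 0.6 to 1337.1 FPKM in HCC827 (7.61 ± 1.05). HSPA1B had 3.41 ± 0.57 and HSPA1A 3.36 ± 0.52, near-identical copies whose reads may be split. The unfolded protein response of the endoplasmic reticulum had a median of 0.86 in NCI-H1975 and -0.10 in HCC827. Over both doses its median in HCC827 was lower by 0.73 (camera on the difference, adjusted p = 6.22e-08; adjusted p = 0.685 with an estimated correlation). Its members HERPUD1 (2.67 ± 0.33), HSPA5 (BiP, 2.14 ± 0.21), DNAJB9 (1.97 ± 0.17) and XBP1 (1.05 ± 0.18) were among the 5 of 20 that rose when adjusted over the list alone (list adjusted p = 0.00126; adjusted p = 0.563 with an estimated correlation).

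Several smaller groups passed the camera test at 5 µM, each with adjusted p = 0.563 with an estimated correlation unless given otherwise. Fatty acid synthesis genes fell (median -0.53, adjusted p = 0.013), with 7 of 12 lower when adjusted over the list alone, such as SCD, the stearoyl-CoA desaturase (-1.54 ± 0.44), and SREBF1, their transcription factor (-1.06 ± 0.24). Tubulin genes rose (median 0.48, adjusted p = 0.00962), with 6 of 13 higher when adjusted over the list alone, led by TUBB2A (2.37 ± 0.68). NRF2 targets rose by camera (median 0.06, adjusted p = 0.0319), but their median was 0.22 in NCI-H1975 and -0.11 in HCC827. HMOX1, heme oxygenase, had 3.20 ± 0.53 and OSGIN1 2.63 ± 0.44. Of the 23 members 9 had negative fitted changes, and 5 were higher and 1, AKR1B10, lower when adjusted over the list alone. Epithelial markers fell (median -0.33, adjusted p = 0.0454; adjusted p = 0.661 with an estimated correlation), with 6 of 15 lower when adjusted over the list alone, including NKX2-1, the lung lineage transcription factor, from 44.72 to 15.76 and from 32.33 to 7.14 FPKM (-1.74 ± 0.28), and MUC1 (-1.71 ± 0.38). Ribosomal protein genes rose slightly (median 0.28, adjusted p = 2.39e-06), 28 of 30 being higher in both lines. Of 12 mesenchymal markers 7 were tested, and they went both ways. When adjusted over the list alone 4 rose, among them SNAI1 (4.02 ± 1.05) and VIM (1.85 ± 0.48), while the other 3 were lower in both lines. The list did not pass (camera, adjusted p = 0.0826).

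Over all 11953 genes tested with limma at 5 µM, 1 passed adjusted p under 0.05: ADM, which encodes the secreted peptide adrenomedullin, rose from 0.37 to 10.79 FPKM in NCI-H1975 and from 25.6 to 292.05 FPKM in HCC827 (log2 change 3.28 ± 0.19, adjusted p = 0.0482, higher in both lines). At unadjusted p under 0.05 there were 3205 genes, 1196 higher and 2009 lower, where chance gives 598. By size, 128 genes were at least 2-fold higher in both lines and 60 at least 2-fold lower, where independent lines would give 15.8 and 9.77. These counts moved with the scale: 105 and 107 with equal FPKM totals, 139 and 32 with quantile normalization, and 214 and 194 with pseudocount 0.1. Ranked by the smaller change of the lines, the top genes besides ADM, at rank 4, were HSPA6, RFPL4A (5.31 ± 0.79), ATF3, ARC (4.23 ± 0.52), DDIT3, RFPL4AL1 (3.82 ± 0.49), DEFB103A (3.37 ± 0.37), ZFAND2A (3.77 ± 0.52) and RASD1 (4.95 ± 1.06). Of these RFPL4A, RFPL4AL1 and DEFB103A have near-identical copies and are uncertain. On the lower side were STS, steroid sulfatase (-1.61 ± 0.25), LAMB1, a laminin chain (-1.50 ± 0.29), NKX2-1, GALNT6 (-1.47 ± 0.20), HMGB3 (-1.45 ± 0.18), LRG1 (-1.48 ± 0.36), ADGRG6 (-1.41 ± 0.21), TNFAIP8L1 (-1.29 ± 0.22), NRP1 (-1.77 ± 0.37) and TNS3 (-1.66 ± 0.28). Adjusted p for the genes named by size was 0.0844 to 0.107. Leaving out 1 library raised the count of 1, from 34 genes without HCC827 DMSO and 80, 99, 230 and 379 without NCI-H1975 at 2.5 µM, HCC827 at 2.5 µM, HCC827 at 5 µM and NCI-H1975 DMSO to 4520 without NCI-H1975 at 5 µM.

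The ADM call ended with no filter on low values (adjusted p = 0.204), with equal FPKM totals (0.0777), without the trend in the prior variance (0.0562), and with the GC and length trend removed (0.066). The ADM log2 change stayed near its size in each, at 3.28, 3.18, 3.28 and 3.23. Besides the autophagosome genes, leaving out 1 library ended the calls of the unfolded protein response (median 0.01, adjusted p = 0.313 without NCI-H1975 at 5 µM; 0.03, 0.348 without its DMSO library), the NRF2 targets (0.313 and 0.0998 without the same libraries) and the epithelial markers (median -0.13, adjusted p = 0.381 without HCC827 at 5 µM). Quantile normalization ended those of the ribosomal (median 0.06, adjusted p = 0.255), tubulin (0.0652) and NRF2 (0.149) lists. With no filter the p53 (0.0537) and NRF2 (0.0542) calls ended, with the GC and length trend removed the NRF2 call (median 0.01, 0.0615), and with pseudocount 0.1 the epithelial call (0.0638). Without NCI-H1975 DMSO or NCI-H1975 at 5 µM the NRF2 median itself was -0.01 or -0.03.

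**Figure D2:**
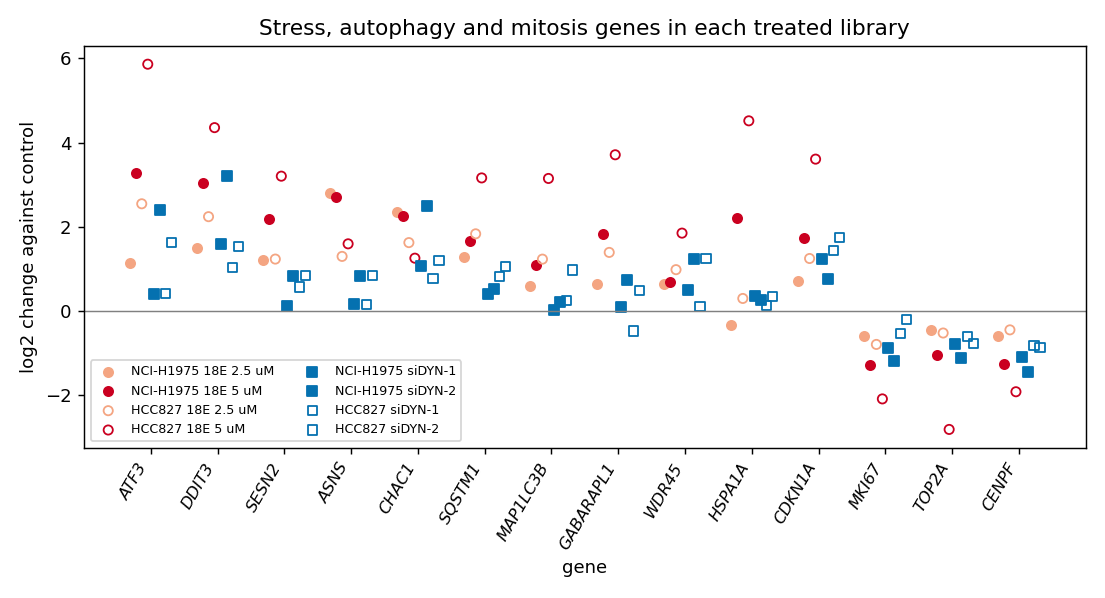
Log2 change of FPKM + 1 (vertical axis) of 14 stress, autophagy and mitosis genes in each of the 8 treated libraries against the control of the same line; circles are 18E, squares siDYN-1 and siDYN-2 from left to right, filled symbols NCI-H1975 and open symbols HCC827. With 5 µM 18E, SQSTM1 lies at 1.67 and 3.16 and TOP2A at -1.03 and -2.81.

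At 2.5 µM 18E ATF4 targets were already elevated. They had a median log2 change of 0.84, with 32 of 34 members higher in both lines, and rose as a group (camera, adjusted p = 1.76e-26; adjusted p = 0.305 with an estimated correlation); 23 rose when adjusted over the list alone against 0 over all genes. ASNS, asparagine synthetase, had 2.05 ± 0.35, CHAC1, which degrades glutathione, 1.99 ± 0.27 (from 1.55 to 11.97 FPKM in NCI-H1975 and from 9.83 to 32.46 FPKM in HCC827), DDIT3 1.87 ± 0.31 and ATF3 1.84 ± 0.56. Among NRF2 targets FTL, the ferritin light chain, went from 553.64 to 1509.78 and from 705.61 to 1958.48 FPKM (1.46 ± 0.15), and HMOX1 from 98.33 to 244.74 and from 2.77 to 46.88 FPKM (2.49 ± 0.53). These were among the 4 of 23 NRF2 targets that rose when adjusted over the list alone, while AKR1B10 fell, and 7 of the 23 had negative fitted changes. The list rose as a group (median 0.14, adjusted p = 0.00552; adjusted p = 0.668 with an estimated correlation).

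G2 and mitosis genes fell at 2.5 µM (median -0.32, camera adjusted p = 4.22e-10; adjusted p = 0.668 with an estimated correlation), 33 of 35 being lower in both lines, with MKI67 at -0.69 ± 0.23 and KIF20A, a mitotic kinesin, at -0.65 ± 0.24; 0 members passed when adjusted over the list alone. Lysosome genes rose slightly (median 0.13, adjusted p = 0.000271; adjusted p = 0.668 with an estimated correlation), with cathepsin L (CTSL) at 1.39 ± 0.29 and TPP1 at 0.63 ± 0.22; 19 of 37 were higher in both lines and 0 passed when adjusted over the list alone. Heat shock genes (median -0.13, adjusted p = 0.342) and the unfolded protein response (median 0.12, adjusted p = 0.162) did not pass. The autophagosome list had a median of 0.08 (adjusted p = 0.067), with GABARAPL1 at 1.02 ± 0.43 and MAP1LC3B at 0.92 ± 0.46, and the autophagy receptor SQSTM1 had 1.57 ± 0.34. In both lists 0 members passed when adjusted over the list alone. Further lists past the threshold were cholesterol synthesis (median -0.18, adjusted p = 0.00134), G1/S (-0.17, 0.000791), hypoxia (-0.16, 0.0228), ribosomal protein (0.16, 0.000119) and interferon-stimulated genes (0.33, 0.00172), with adjusted p = 0.668, 0.694, 0.668, 0.668 and 0.794 with an estimated correlation.

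No gene passed adjusted p under 0.05 at 2.5 µM with limma (smallest adjusted p = 0.534). At unadjusted p under 0.05 there were 629 genes, where chance gives 598. By size, 30 genes were at least 2-fold higher in both lines and 1 at least 2-fold lower, where independent lines would give 1.00 and 0.15. These were 82 and 11 with pseudocount 0.1, and 2 were lower with quantile normalization, with equal FPKM totals or with the GC and length trend removed. The genes named by size were VGF (1.88 ± 0.36), CHAC1, PCK2, the mitochondrial PEPCK (1.59 ± 0.42), H4C8, a histone gene with near-identical copies (1.71 ± 0.39), DDIT3, CTH, cystathionine gamma-lyase (1.54 ± 0.15), FTL, UPP1 (1.87 ± 0.22), HSPB8 (1.42 ± 0.49) and HMOX1 on the higher side. On the lower side were NT5E (CD73, -1.01 ± 0.22), ARHGDIB (-1.04 ± 0.21), AKR1B10 (-1.11 ± 0.20), TCAF2 (-0.90 ± 0.16), SPTB (-1.07 ± 0.19), CRYBG1 (-0.91 ± 0.18), ANKRD22 (-0.87 ± 0.18), SEMA4B (-0.83 ± 0.23), GALNT10 (-0.85 ± 0.19) and AIF1L (-0.79 ± 0.18). The count of 0 became 3, 22, 24 and 26 without HCC827 DMSO, NCI-H1975 at 5 µM, NCI-H1975 DMSO and HCC827 at 5 µM. Leaving out 1 library also ended several of the smaller list calls: without HCC827 DMSO the median and adjusted p were -0.04 and 0.977 for G1/S, -0.08 and 0.505 for cholesterol synthesis, -0.08 and 0.948 for hypoxia and 0.06 and 0.0926 for lysosome genes. Without HCC827 at 2.5 µM the adjusted p was 0.051, 0.0547 and 0.0688 for G1/S, hypoxia and lysosome genes. Interferon-stimulated genes then went to a median of -0.11. Without NCI-H1975 DMSO it was 0.064 for NRF2 targets, 0.051 for ribosomal protein genes and 0.0682 for interferon-stimulated genes, and pseudocount 0.1 ended the hypoxia call (0.0698).

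The doses were compared directly. Heat shock genes were higher at 5 than at 2.5 µM (median difference 1.54, all 19 positive, camera adjusted p = 2.84e-17; adjusted p = 0.526 with an estimated correlation), and 16 rose when adjusted over the list alone. The median difference was 0.58 without HCC827 at 5 µM and 2.44 without NCI-H1975 at 5 µM, with the camera call kept in each. G2 and mitosis genes were lower (median -0.58, adjusted p = 2.88e-09; adjusted p = 0.548 with an estimated correlation), 34 of 35 being negative, and autophagosome genes higher (median 0.11, adjusted p = 0.00148; adjusted p = 0.659 with an estimated correlation). Without HCC827 at 5 µM the autophagosome median was -0.05 (adjusted p = 0.556). The ATF4 targets were not among the 16 lists past the threshold. No single gene passed (smallest adjusted p = 0.131), and 1405 had an unadjusted p under 0.05 with limma. The count of 0 became 1, 4, 36, 37 and 3478 without HCC827 at 2.5 µM, HCC827 at 5 µM, HCC827 DMSO, NCI-H1975 DMSO and NCI-H1975 at 5 µM.

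**Figure D3:**
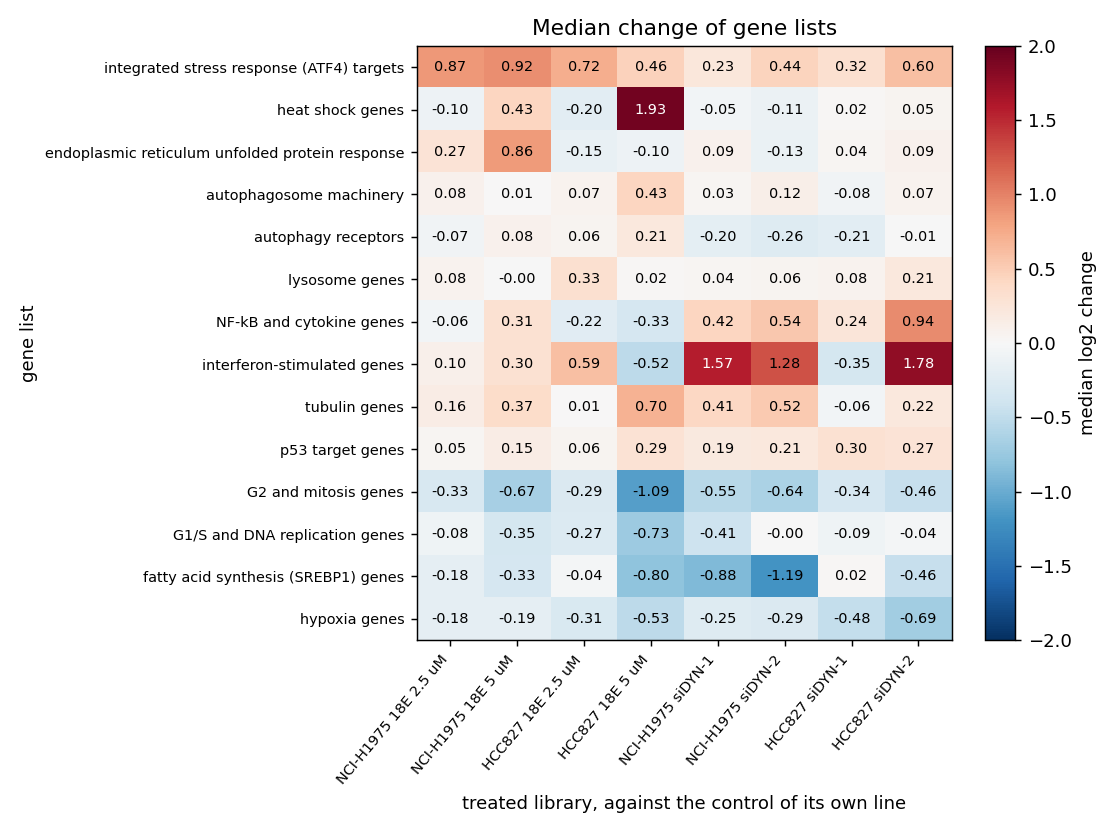
Median log2 change of 14 gene lists in the 8 treated libraries against the control of the same line, with the value in each cell and colour from blue (lower) to red (higher). ATF4 targets lie between 0.23 and 0.92 and G2 and mitosis genes between -0.29 and -1.09 in all 8 libraries, while heat shock genes reach 1.93 in HCC827 at 5 µM 18E.

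The siRNA experiment asked which genes changed when DYNC1LI1 was lowered. Inflammatory genes were higher: CCL20, a chemokine, went from 8.56 FPKM with siCON to 41.06 and 72.31 FPKM with siDYN-1 and siDYN-2 in NCI-H1975, and from 115.08 to 425.39 and 613.7 FPKM in HCC827 (log2 change 2.34 ± 0.26, SE). The neutrophil chemokines CXCL1 (1.65 ± 0.23) and CXCL8 (1.56 ± 0.50) and the cytokine IL6 (1.71 ± 0.73) completed the 4 largest changes of the NF-kB and cytokine list, which rose as a group (median 0.56, camera adjusted p = 6.18e-05; adjusted p = 0.723 with an estimated correlation). Of its 23 members 15 were higher in all 4 libraries, and 5 rose when adjusted over the list alone against 0 over all genes. Interferon-stimulated genes rose as a group too (median 1.05, adjusted p = 6.18e-05; adjusted p = 0.723 with an estimated correlation), with medians of 1.57 and 1.28 in NCI-H1975 and 1.78 in HCC827 with siDYN-2 but -0.35 in HCC827 with siDYN-1. IFI6 had 2.58 ± 0.57 and IFI27 2.49 ± 0.54, and 3 of the 25 rose when adjusted over the list alone. The antigen-presentation genes CD74, the MHC class II invariant chain (1.75 ± 0.19), and HLA-B (1.93 ± 0.30) were among the genes named by size.

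Mitotic genes fell with siDYN (median -0.49, camera adjusted p = 4.44e-10; adjusted p = 0.723 with an estimated correlation). Of 35 members, 28 were lower in all 4 libraries and 21 fell when adjusted over the list alone, including ANLN, which organises the cleavage furrow (-1.16 ± 0.29), CENPF (-1.06 ± 0.18) and TOP2A (-0.81 ± 0.15). ATF4 targets rose (median 0.46, adjusted p = 9.75e-05; adjusted p = 0.723 with an estimated correlation), 21 of 33 being higher in all 4 libraries, with DDIT3 at 1.84 ± 0.47 and CHAC1 at 1.39 ± 0.40, and 5 rose when adjusted over the list alone. Fatty acid synthesis genes fell (median -0.61, adjusted p = 0.00166; adjusted p = 0.723 with an estimated correlation): SCD went from 165.23 to 32.85 and 15.99 FPKM in NCI-H1975 and from 89.22 to 46.98 and 32.49 FPKM in HCC827 (-1.98 ± 0.43), and FASN had -1.03 ± 0.22. Only 4 of its 12 members were lower in all 4 libraries, and the list median in HCC827 with siDYN-1 was 0.02. The list's call ended without NCI-H1975 siCON (median -0.27, adjusted p = 0.137). Hypoxia genes fell (median -0.36, adjusted p = 0.000632; adjusted p = 0.723 with an estimated correlation), led by LDHA (-0.74 ± 0.18), a call that ended without HCC827 siCON (median -0.24, adjusted p = 0.194). Nuclear genes of oxidative phosphorylation rose (median 0.33, adjusted p = 0.000239; adjusted p = 0.723 with an estimated correlation), 22 of 29 being higher in all 4 libraries, a call that quantile normalization ended (median 0.13, adjusted p = 0.0875). Against random lists of like expression its median stood at percentile 99.8 and 97.8 in NCI-H1975 with siDYN-1 and siDYN-2, and at 98.4 and 78.4 in HCC827. The BCL2 family rose by camera (median 0.40, adjusted p = 0.0171, and adjusted p = 0.723 with an estimated correlation), with BIK at 1.12 ± 0.14 and BAK1 at 0.81 ± 0.22. Only 6 of its 14 members were higher in all 4 libraries, and its median in HCC827 with siDYN-1 was 0.06. The BCL2 call ended with the GC and length trend removed (median 0.28, adjusted p = 0.0981).

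Autophagosome genes did not pass as a group with siDYN (median 0.05 over 39 genes, camera adjusted p = 0.509), and 0 passed when adjusted over the list alone. MAP1LC3B had a log2 change of 0.37 ± 0.23 and GABARAPL1 of 0.21 ± 0.31, both named here because of their values with 18E. Among 15 autophagy receptors, SQSTM1 rose (0.70 ± 0.16) and 4 fell when adjusted over the list alone, against 0 over all genes. The 4 included the mitophagy receptors BNIP3L (-0.85 ± 0.13) and BNIP3 (-0.63 ± 0.18) and CALCOCO2 (NDP52, -0.54 ± 0.14). The receptors as a list (median -0.19, adjusted p = 0.318), the lysosome genes (median 0.12, adjusted p = 0.404) and the heat shock genes (median -0.06, adjusted p = 0.923) did not pass.

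No gene passed adjusted p under 0.05 over the 11718 tested with limma. The smallest adjusted p was 0.0784, which DYNC1LI1 itself had (log2 change -2.48 ± 0.25, lower in 4 of 4 libraries), 420 genes were under 0.1 (257 higher, 163 lower), and 3042 had an unadjusted p under 0.05, where chance gives 586. By size, 27 genes were at least 2-fold higher in all 4 libraries and 4 at least 2-fold lower, where independent lines would give 1.08 and 0.0943. These were 63 and 13 with pseudocount 0.1 and 18 and 8 with equal FPKM totals, and 2 were lower with the GC and length trend removed. The 10 higher genes named by size also held TMPRSS11E (1.92 ± 0.23), PLAAT2 (2.08 ± 0.35), H2BC5 (1.85 ± 0.23), S100A2 (2.18 ± 0.32), EMC6 (1.41 ± 0.13), C19orf33 (1.43 ± 0.14) and CKMT1A (2.08 ± 0.34); H2BC5 and CKMT1A have near-identical copies. On the lower side were ASPH (-1.72 ± 0.31), LPGAT1 (-1.19 ± 0.14), TAF9B (-1.39 ± 0.18), RHOBTB3 (-1.21 ± 0.16), AK4 (-1.19 ± 0.16), FAM168B (-0.99 ± 0.13), IL6ST, the gp130 receptor (-1.23 ± 0.22), SCD and RAB6A, a Golgi GTPase (-1.07 ± 0.17). Without HCC827 siDYN-1 the fit called 128 genes, 118 higher and 10 lower. With each siRNA as its own level it called 82 genes for siDYN-1 and 2124 for siDYN-2.

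The lines were compared for each treatment. Log2 changes of the lines correlated across genes with Pearson's r = 0.52 at 5 µM and 0.39 at 2.5 µM (Spearman 0.46 and 0.40), from 1 library per line. For siDYN r was 0.68 (Spearman 0.70) between the means of the 2 siRNAs in each line. Averaging lowers noise, so the siDYN value cannot be ranked against those of 18E. Genes are not independent replicates, so no p is given. The test of a difference between the lines called 0 genes for 18E and 0 for siDYN with limma, with 205 and 178 at unadjusted p under 0.05. For 18E the genes with the smallest p included CLDN2, a tight junction claudin (mean change -2.56 in HCC827 and -0.03 in NCI-H1975), and DHRS2 (3.15 and -1.17), all with adjusted p = 0.999. For siDYN they were U2AF1, a splicing factor with a near-identical copy (-3.64 in HCC827 and 0.40 in NCI-H1975, adjusted p = 0.264), and CT45A7, of a family of near-identical copies (0.06 and 3.86, adjusted p = 0.264). The HCC827 library at 5 µM stood apart: its changes had an SD of 0.79 against 0.44 in NCI-H1975, 884 genes were at least 2-fold higher and 865 lower against 213 and 135, and 534 genes were listed at 0 against 1395 in its DMSO library.

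The last question was whether 18E and the knockdown moved the same genes; these experiments share no libraries. Across 11449 genes the mean changes correlated with Pearson's r = 0.32 (Spearman 0.29), 0.43 within NCI-H1975 and 0.20 within HCC827. By siRNA, r was 0.36 with siDYN-1 and 0.44 with siDYN-2 in NCI-H1975, and 0.07 (Spearman 0.05) with siDYN-1 and 0.26 with siDYN-2 in HCC827. The 200 genes highest with 5 µM 18E had a median log2 change of 0.44 with siDYN, 161 of them higher (camera, adjusted p = 2.73e-10; adjusted p = 0.201 with an estimated correlation), and the 200 lowest a median of -0.38, 171 of them lower (adjusted p = 1.06e-13; adjusted p = 0.131 with an estimated correlation). The 200 highest with siDYN had a median of 0.26 with 18E, 130 of them higher (adjusted p = 8.35e-10; adjusted p = 0.104 with an estimated correlation), and the 200 lowest -0.50, 168 of them lower (adjusted p = 1.89e-11; adjusted p = 0.0739 with an estimated correlation). Among the fixed lists, ATF4 targets rose and G2 and mitosis and fatty acid synthesis genes fell by camera with both 5 µM 18E and siDYN. With an estimated correlation each lost its call (adjusted p = 0.563 for 18E and adjusted p = 0.723 for siDYN with an estimated correlation). Medians of other lists with 5 µM 18E and with siDYN, whose difference was not tested, were 1.18 and -0.06 for heat shock genes, 0.28 and 0.06 for ribosomal protein genes and -0.08 and 1.05 for interferon-stimulated genes. They were 0.48 and 0.44 for tubulin genes, -0.32 and -0.36 for hypoxia genes and 0.19 and 0.29 for p53 targets. With siDYN the tubulin (camera, adjusted p = 0.133), p53 (0.234) and ribosomal protein (0.39) lists did not pass. With 5 µM 18E the hypoxia (0.263) and interferon (0.692) lists did not pass, and the interferon median was 0.30 in NCI-H1975 and -0.52 in HCC827.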

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

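The tests of gene lists between the lines were chosen after the data were seen, as were the GC and length correction and the tests of a shared response to the knockdown, of loss of the target and of a stronger response of HCC827. The tests of low values, and of the GC and length trend in the spread, were set before their values were seen.

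For 18E, 9 gene lists differed between the lines by camera on the interaction, with values as the median of HCC827 minus NCI-H1975. The unfolded protein response was lower in HCC827 (-0.73, adjusted p = 6.22e-08), as were NF-kB and cytokine genes (-0.47, 0.000667), ATF4 targets (-0.31, 0.0178), hypoxia genes (-0.31, 0.00926), G1/S genes (-0.28, 0.00123), oxidative phosphorylation genes (-0.24, 0.0034) and cholesterol synthesis genes (-0.22, 0.0174). Autophagosome genes (0.24, 0.00926) and lysosome genes (0.17, 0.0425) were higher in HCC827. For siDYN, 6 lists differed: fatty acid synthesis (0.73, 3.62e-06), cholesterol synthesis (0.37, 1.63e-05) and G2 and mitosis genes (0.19, 0.0348) were higher in HCC827, and interferon-stimulated genes (-0.90, 5.77e-05), tubulin genes (-0.38, 0.00754) and hypoxia genes (-0.33, 0.000363) lower. With an estimated correlation each lost its call (adjusted p = 0.685 for 18E and 0.963 for siDYN). Leaving out 1 library ended several of the 18E calls. Without HCC827 at 5 µM autophagosome genes had adjusted p = 0.756. Without HCC827 at 2.5 µM it was 0.405 for lysosome genes, 0.141 for NF-kB genes, 0.0702 for ATF4 targets and 0.123 for cholesterol synthesis. Without NCI-H1975 at 5 µM it was 0.0526 for lysosome genes, 0.122 for ATF4 targets, 0.117 for cholesterol synthesis, 0.0727 for hypoxia and 0.0611 for oxidative phosphorylation, and without NCI-H1975 at 2.5 µM 0.0775 for lysosome genes. For siDYN, without HCC827 siDYN-1 interferon genes went to 0.02 (adjusted p = 0.773), G2 and mitosis genes to adjusted p = 0.64 and tubulin genes to 0.098. Without NCI-H1975 siDYN-2 it was 0.331 for G2 and mitosis and 0.101 for tubulin genes, and without NCI-H1975 siDYN-1 0.107 for interferon genes. Other settings ended calls too. For 18E these were lysosome genes (pseudocount 0.1, 0.102; no filter, 0.216), autophagosome genes (no filter, 0.0607), and with quantile normalization ATF4 targets (0.0816), cholesterol synthesis (0.055) and oxidative phosphorylation (0.0758). For siDYN they were G2 and mitosis genes (pseudocount 0.1, 0.0903; GC and length trend removed, 0.0851).

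Changes with 5 µM 18E and with siDYN correlated across genes (r = 0.32). After the GC and length trend was removed from each library r was 0.32, and among 6118 genes with a mean of at least 10 FPKM it was 0.31, so neither that trend nor values near the floor account for it. By siRNA r was 0.07 in HCC827 with siDYN-1, although DYNC1LI1 was at 14.9% of siCON there, and 0.26 to 0.44 in the other 3 libraries. A shared response to less activity of the siRNA target would be one candidate explanation, but the largest adjusted p of the 4 gene sets was 0.201 with an estimated correlation, and slower growth or general stress in both experiments would give the same. These cannot be told apart here, because each experiment has 1 library per line and treatment and no unrelated stressor.

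Interferon-stimulated genes were higher in 3 of the 4 siDYN libraries. The smallest of those 3 medians was 1.38 after the GC and length trend was removed, which argues against the trend as the cause. A response to loss of DYNC1LI1 was taken, after the data were seen, to give a rise in all 4. The median in HCC827 with siDYN-1 was -0.35, with DYNC1LI1 at 14.9% of siCON. In HCC827 with siDYN-2 it was 1.78 at 7.49% of siCON, and in NCI-H1975 with siDYN-1 1.57 at 21.5%. The rule does not cover a response that differs by line or by depth of the knockdown. As the exception is 1 library it leaves the explanation open, beside a response to transfected RNA that differed between cultures, which was not tested.

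The HCC827 library at 5 µM had wider changes than NCI-H1975 (SD 0.79 against 0.44, a ratio of 1.80). Among 6323 genes with a mean of at least 10 FPKM the ratio was 1.84, and with the GC and length trend removed it was 1.84, so low values and that trend do not account for it. A stronger response of HCC827 may be the reason. The test of the difference (205 genes at unadjusted p under 0.05, where chance gives 598) averages the doses and takes their difference as spread, so a response at 5 µM alone widens its own error and the count weighs neither for nor against. There is 1 library per line at that dose. The response and a property of that 1 library cannot be told apart.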

How the results depend on the processing

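The GC and length correction, the threshold of 0.1, the estimated correlation for the sets of 200 genes, and equal totals for lists, correlations and 2-fold counts were chosen after the data were seen.

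The 1 gene called for 18E 5 µM vs DMSO became 16 with pseudocount 0.1, 11 at a threshold of 0.1, and 0 with no filter on low values, with equal FPKM totals, with eBayes without trend, with no cell line term, with both doses pooled as treated, and with the GC and length trend removed. For siDYN vs siCON the 0 became 82 for siDYN-1 as its own level, 2124 for siDYN-2 as its own level and 420 at a threshold of 0.1. The siDYN effect by cell line called 1 gene with pseudocount 0.1. Of the gene lists for 18E 5 µM, 18E 2.5 µM and siDYN, 12, 9 and 8 were called, and 0, 0 and 0 by camera with estimated correlation. The latter test had little power in the simulated data.

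For the similarity of 18E and siDYN, camera with estimated correlation left the medians of 0.44, -0.38, 0.26 and -0.50 without a call. Genes changed at least 2-fold in both lines, higher and lower, were 214 and 194 at 5 µM, 82 and 11 at 2.5 µM and 63 and 13 for siDYN with pseudocount 0.1. The lower ones at 5 µM, 2.5 µM and siDYN were 107, 2 and 8 with equal FPKM totals and 35, 2 and 2 with the GC and length trend removed, and with quantile normalization those at 5 µM and 2.5 µM were 32 and 2. The similarity of the lines at 18E 2.5 µM was 0.32 with pseudocount 0.1.

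Leaving out 1 library, with a lone library assumed to vary like the others, gave 34 to 4520 genes for 18E 5 µM vs DMSO, 0 to 26 for 2.5 µM vs DMSO, 0 to 3478 for 5 µM vs 2.5 µM and 0 to 128 for siDYN vs siCON. Without a control library the difference between lines cannot be estimated and was not run.

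Leave-outs turned the camera direction of some lists that passed before or after. Their medians over all alternatives are given from lowest to highest. Medians of other lists crossed 0 too, such as the NF-kB and cytokine genes at 5 µM (-0.35 to 0.27). For 18E 5 µM vs DMSO interferon-stimulated genes ran from -0.61 to 0.40. For 18E 2.5 µM vs DMSO the unfolded protein response of the endoplasmic reticulum ran from -0.28 to 0.40, heat shock genes from -0.58 to 0.26 and interferon-stimulated genes from -0.11 to 0.79. For 18E 5 µM vs 2.5 µM interferon-stimulated genes ran from -1.03 to 0.17. For the 18E effect by cell line heat shock genes ran from -0.39 to 1.84, interferon-stimulated genes from -0.66 to 0.42 and epithelial markers from -0.45 to 0.33. For the siDYN effect by cell line interferon-stimulated genes ran from -1.82 to 0.0164 and cytosolic ribosomal protein genes from -0.14 to 0.19. Quantile normalization turned the cytosolic ribosomal protein genes in 18E 5 µM vs 2.5 µM to -0.0540.

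Among the other values, called lists kept their call in 268 and lost it in 91 under other settings, and kept it in 275 and lost it in 51 leave-outs. Lists not called stayed so in 558 and passed in 18 under other settings, against 440 and 54 in leave-outs. Named genes stayed on their side of the threshold in 352, passed in 4 and lost the call in 4 under other settings. Only ADM at 5 µM was called among them, so nearly all stayed without a call. The 4 lost calls were those of ADM.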

Other observations

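The members of fixed lists named here were chosen after their values were seen. HBEGF, an EGFR ligand, had a log2 change of 3.65 ± 0.66 (SE) at 5 µM and the MAPK phosphatase DUSP5 1.94 ± 0.52, while the ligand EREG had -1.63 ± 0.48 and the feedback inhibitor SPRY1 -1.35 ± 0.22. With MYC (1.39 ± 0.17) and IER3 (1.46 ± 0.26), these were among the 4 higher and 3 lower of 21 EGFR and MAPK output genes that passed when adjusted over the list alone; the list went both ways and did not pass (adjusted p = 0.278). In the hypoxia list, ADM (3.28 ± 0.19) and ANKRD37 (1.24 ± 0.32) were higher while the glycolytic LDHA (-0.99 ± 0.23) and the oxygen sensor EGLN3 (-0.78 ± 0.17) were lower when adjusted over the list alone, and the list did not pass (median -0.32, adjusted p = 0.263).

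With siDYN the same EGFR and MAPK list held ETV1 (-1.10 ± 0.18) and CCND1, cyclin D1 (-0.71 ± 0.14), among 5 lower genes, and IER3 (1.00 ± 0.21) and EPHA2 (0.73 ± 0.18) as the 2 higher, when adjusted over the list alone (list adjusted p = 0.509). Epithelial genes CDH1, E-cadherin (-0.92 ± 0.15), NKX2-1 (-0.69 ± 0.20) and ESRP1 (-0.54 ± 0.14) fell and MUC1 (0.94 ± 0.31) rose when adjusted over the list alone; the list did not pass with camera (adjusted p = 0.12). With 5 µM 18E CDH1, NKX2-1 and ESRP1 were lower (-0.82 ± 0.24, -1.74 ± 0.28 and -0.85 ± 0.18), and MUC1, opposite to siDYN, was lower as well (-1.71 ± 0.38). The dynactin subunit DCTN4 fell (-0.76 ± 0.16) and the adaptor BICD2 rose (0.60 ± 0.14) when adjusted over the list alone; the list did not pass (adjusted p = 0.509).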
